A study of Caenorhabditis elegans with 18 samples.

How the data were processed

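RNA was extracted from N2 and hira-1(-) animals grown at 20°C on bacterial lawns, selected by poly(A) tail, and sequenced from paired ends, per the labels' protocols. The authors deposited 2 gene tables with 18 columns each. The first holds estimated counts per gene as RSEM writes them (expected counts that need not be whole numbers), per the deposited file's values and the submitters' processing notes. Those notes name Bowtie 1.0.1, RSEM 1.2.15, SAMtools 0.1.19 and the ce10 genome build. The second table holds FPKM values on a log2 scale after adding 1, as deposited by the authors. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes may share reads. RSEM divides reads that match several genes by its model, so near-identical genes (histones, major sperm proteins, pud-2.1 and pud-2.2) carry uncertain values.

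Of the 18 columns, 8 have names that match the labels of 1 sample each, namely replicates 1 and 2 of both genotypes at L4 and in adults (1 name was matched in spite of a digit in place of a letter). The other 10 columns match no label and were not used in any step. The comparisons planned for L1, the interactions with L1 and the planned test of the genotype difference along the N2 stage axis therefore could not be made. The designs were written for all 18 libraries in 6 groups and were fitted to the 8 libraries in 4 groups, with 4 residual degrees of freedom. Gene names come from a reference table of assembly WBcel235, which differs from the build of the files, so no coordinates are given. Of 45461 rows, 44080 matched the table by sequence name.

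Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the expression filter with its default minimum count of 10 (and 15 in total), a quasi-likelihood fit of the 4 group means with robust dispersion, and Benjamini-Hochberg adjustment with a threshold of 0.05. The fit pools the spread of all 8 libraries. The filter kept 16770 genes, and the common biological coefficient of variation was 6.26%. Expression is given as CPM, the estimated count divided by the TMM-scaled library size and brought to edgeR's common scale. Adjusted p-values in the text are from this test unless another is named. A gene whose libraries of 1 group are all at 0 is compared with a floor of 3 counts per library, and for genes with 1 to 3 counts over a group the ratio has an exact 95% binomial interval. Libraries held 26010300 to 31174600 estimated counts, and replicates of a group differed by more than counting noise (chi-square per degree of freedom 5.77 to 19.3). Library preparation alone can give such a spread. The replicates were treated as separate samples, as the labels list them.

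Before the data were examined, 39 gene lists (tissues, germ cells, cuticle, stress, chromatin), the named-gene rule, the tests and most alternatives were fixed. Lists with at least 5 tested members (38 of them) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. With fewer, values are given without a list test. The estimated correlation also limits camera to the 4 residual degrees of freedom, so a call lost with it need not come from correlated genes. The named-gene rule took, per genotype comparison, genes past the threshold with non-overlapping libraries and a mean of at least 5 CPM in the higher genotype: the 8 largest changes per direction with a 3- or 4-letter name and the 2 largest with a sequence name only. It added up to 4 members per list with the smallest adjusted p (the text gives the first 2 of some lists, and which lists get examples was chosen after their values were seen), all members of the H3.3 and chaperone lists, the 4 largest per direction for the interaction and the N2 comparison, the 10 largest shared by the stages, and hira-1. The rule was written for 3 libraries per group and 3 stages and was applied to 2 of each. The H3.3 gene his-69 was not among the genes tested.

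Alternatives were RLE scaling, library totals, no filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, only the groups compared, a block for the replicate number, a test against a 1.5-fold minimum, limma on the deposited log2 FPKM values, fits without the ribosomal RNA genes, and leaving out each library in turn. Library totals and the fits without ribosomal RNA were added after seeing the data. The fit was tested on simulated counts with 200 genes changed by known folds, drawn for the real genes and library sizes. At L4, 84% of genes changed 2-fold and 68% of those changed 1.5-fold were recovered among 16476 genes, with 22 unchanged genes called. In adults these were 84% and 56% among 16413 genes, with 6 called. For the interaction they were 56% and 38% among 16495 genes. That simulation capped the stage-specific ratio of some genes, so its 83 other calls are not all errors. Few genes changed in the simulations, up and down in equal number, whereas 58.0% at L4 and 55.1% in adults passed in the data. These rates therefore do not give the power or the false calls of the real comparisons, and they do not test the scaling.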

Results

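RNA from Caenorhabditis elegans was sequenced after poly(A) selection in the wild-type strain N2 and in animals carrying the hira-1(gk835598) allele, written hira-1(-). HIRA is a histone chaperone that deposits the histone variant H3.3 outside replication. The series holds 18 samples of both genotypes at the L1 and L4 larval stages and in adults. The values below come from 8 libraries, 2 per genotype at L4 and in adults, and the L1 samples and the replicates numbered 3 were not analysed here. The libraries held between 26010300 and 31174600 estimated counts. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

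Stage and genotype separated the libraries. The first principal component of log2 CPM held 73.7% of the variance and separated the stages, and the second held 17.3% and separated the genotypes. On the first component the N2 L4 libraries lay at -131 and -128 and the N2 adult libraries at 132 and 132. The hira-1(-) libraries lay between them, at -91.9 and -92.0 for L4 and at 91.7 and 87.1 for adults. The mean Spearman correlation between L4 and adult libraries, across genes, was 0.822 in N2 and 0.891 in hira-1(-). The lowest correlation between replicates of a group was 0.9947.

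The targeted gene was measured first. The hira-1 transcript (K10D2.1) was present in all 8 libraries and lower in hira-1(-) at both stages. It went from 35.1 ± 3.2 to 24.5 ± 1.1 CPM at L4 (SD, n = 2 per group; log2 fold change -0.52, SE 0.07, adjusted p = 3.3e-05). In adults it went from 109 ± 0.78 to 40.4 ± 0.44 CPM (SD, n = 2; log2 fold change -1.43, SE 0.06, adjusted p = 2.0e-09). The fall was larger in adults than at L4 (difference in log2 fold change -0.91, SE 0.10, adjusted p = 5.6e-06). All 8 histone chaperone genes, hira-1 among them, differed this way between the stages (median difference -0.73). The stage difference is therefore not particular to hira-1. In N2 the transcript was higher in adults than at L4 (log2 fold change 1.63, adjusted p = 4.5e-11). The series design text calls the mutant animals hira-1 null. The labels do not say what the allele changes in the transcript, so the presence of the transcript does not go against the labels. Other differences between the strains cannot be told apart from an effect of the allele.

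At L4, the question was which genes differ between hira-1(-) and N2 larvae. Oocyte, germ line and cell cycle genes were higher in hira-1(-). All 27 oocyte and eggshell genes were higher (median log2 fold change 1.79, interquartile range 1.57 to 2.43; camera adjusted p = 5.5e-49). The Pumilio family genes puf-5 (F54C9.8) and puf-3 (Y45F10A.2), which act in oocyte formation, went from 17.0 ± 1.2 to 167 ± 1.3 CPM (log2 fold change 3.296, SE 0.06, adjusted p = 1.2e-12) and from 22.8 ± 2.8 to 127 ± 1.3 CPM (log2 fold change 2.48). Of 46 other germ line genes, 44 were higher and none was lower (median 0.79; adjusted p = 7.0e-17). The Piwi protein gene prg-1 (D2030.6) went from 227 ± 1.2 to 613 ± 7.3 CPM (log2 fold change 1.43), and the nuclear Argonaute gene hrde-1 (C16C10.3) from 156 ± 5.7 to 375 ± 4.1 CPM (log2 fold change 1.27). All 43 cell cycle and replication genes were higher (median 0.65; adjusted p = 2.5e-16), among them the cyclin B genes cyb-2.1 (log2 fold change 2.00) and cyb-2.2 (log2 fold change 1.93). Of 18 DNA damage genes, 17 were higher (median 0.66; adjusted p = 3.1e-06). With an estimated correlation these 4 lists did not pass (adjusted p = 0.216 with an estimated correlation for each). The members higher when adjusted over the list alone were 27, 45, 43 and 18.

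Sperm genes were also higher at L4. Of 32 major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, 29 were higher and 2 lower (median 1.08; adjusted p = 4.4e-14, and adjusted p = 0.24 with an estimated correlation). The gene msp-38 went from 20.0 ± 1.2 to 70.5 ± 2.5 CPM (log2 fold change 1.82) and msp-45 from 34.6 ± 0.55 to 86.6 ± 1.4 CPM (log2 fold change 1.32). Of 67 other sperm genes, 39 were higher and 9 lower (median 0.48; adjusted p = 0.0019, and adjusted p = 0.6 with an estimated correlation). In these lists 29 and 39 members were higher adjusted over the list alone. Copies of the major sperm protein genes are nearly identical, and estimated counts may be split between copies in either list.

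Genes of H3.3 and of histone chaperones differed too. The H3.3 gene his-72 (Y49E10.6) went from 128 ± 8.2 to 383 ± 5.7 CPM at L4 (log2 fold change 1.58, SE 0.05, adjusted p = 1.9e-10). The H3.3 gene his-74 went from 63.1 ± 1.6 to 97.3 ± 4.6 CPM (log2 fold change 0.62, adjusted p = 4.4e-07). The change of his-71 was small (log2 fold change 0.19, SE 0.07, adjusted p = 0.0243) and did not pass with DESeq2 (adjusted p = 0.115) or without N2 L4 replicate 1 or 2 (adjusted p = 0.787 and 0.173) or hira-1(-) L4 replicate 1 or 2 (adjusted p = 0.08 and 0.129). For his-70 the log2 fold change was -0.05 (adjusted p = 0.671). Of 8 histone chaperone genes, hira-1 was lower and the other 7 were higher (median 0.63; adjusted p = 0.0104, and adjusted p = 0.24 with an estimated correlation; 7 higher and 1 lower adjusted over the list alone). These were the ASF1 genes asfl-1 (1.00) and unc-85 (0.64), the CAF-1 genes chaf-1 (0.66), chaf-2 (0.31), rba-1 (0.67) and lin-53 (0.62), and the ATRX gene xnp-1 (0.35), all as log2 fold changes. The median of the chaperone list lay near those of the cell cycle (0.65), DNA damage (0.66) and germ line lists (0.79). A rise particular to chaperones is therefore not shown. In N2 all 8 chaperone genes were higher in adults than at L4 (median 1.72). Without N2 L4 replicate 1 the calls of chaf-2 (adjusted p = 0.107) and of the histone chaperones as a list (adjusted p = 0.0575) were lost. Of 58 core histone genes, 36 were higher and 4 lower (median 1.00; adjusted p = 1.1e-06, and adjusted p = 0.24 with an estimated correlation; 37 higher adjusted over the list alone). The gene his-11 went from 4.20 ± 0.32 to 27.1 ± 0.63 CPM and his-26 from 1.195 ± 0.28 to 17.1 ± 0.80 CPM. Core histone genes share reads with near-identical copies, and most of their transcripts lack the poly(A) tail used for selection, so their values are uncertain.

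Muscle, cuticle and yolk genes were lower at L4. Of 27 body wall muscle genes, 24 were lower and none was higher (median -0.77; adjusted p = 1.2e-10, and adjusted p = 0.312 with an estimated correlation). Actin act-1 went from 2688 ± 274 to 1142 ± 35 CPM (log2 fold change -1.23) and the muscle gene dim-1 from 842 ± 58 to 442 ± 9.1 CPM (log2 fold change -0.93). Of 160 cuticle collagen genes, 81 were lower and 30 higher (median -0.73; adjusted p = 2.5e-10, and adjusted p = 0.24 with an estimated correlation). The collagen genes col-38 and col-175 went from 2329 ± 81 to 767 ± 14 CPM and from 1501 ± 69.7 to 505 ± 12 CPM. The 6 vitellogenin genes, which encode yolk proteins, were all lower (median -1.74; adjusted p = 2.1e-04, and adjusted p = 0.331 with an estimated correlation), with vit-3 at 432 ± 111 to 46.2 ± 2.9 CPM and vit-4 at 207 ± 44 to 43.2 ± 1.7 CPM. Of 43 hedgehog-related genes, 21 were lower and 11 higher (median -0.52; adjusted p = 0.0019, and adjusted p = 0.216 with an estimated correlation; 22 lower adjusted over the list alone). Of 47 molting genes, 21 were lower and 13 higher (median -0.17, and -0.03 with library totals; adjusted p = 0.0074, and adjusted p = 0.24 with an estimated correlation; 23 lower adjusted over the list alone). Of 40 mitochondrial respiration genes, 31 were lower and 2 higher (median -0.30, and -0.17 with library totals; adjusted p = 7.2e-05, and adjusted p = 0.418 with an estimated correlation). Of 87 fatty acid metabolism genes, 47 were lower and 17 higher (median -0.31, and -0.17 with library totals; adjusted p = 2.8e-05, and adjusted p = 0.24 with an estimated correlation). Pan-neuronal genes did not pass as a list, with 6 higher and 7 lower of 23 (median -0.06, 0.08 with library totals; adjusted p = 0.543). The numbers lower were 26 muscle, 85 collagen, 6 vitellogenin, 31 respiration and 47 fatty acid genes when adjusted over the list alone.

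The largest single changes at L4 were in both directions. The genes pud-4 and pud-3 went from 128 ± 6.8 to 1.21 ± 0.22 CPM (log2 fold change -6.73, SE 0.12, adjusted p = 2.9e-12) and from 409 ± 19 to 7.47 ± 0.80 CPM (log2 fold change -5.77). Their relatives pud-1.1 (-4.21) and pud-1.2 (-4.08) were lower too, on the log2 scale. Among the 8 largest falls were also gtnt-17 (-4.72), gtnt-18 (-4.65), gly-1 (-4.69, and -3.98 and -6.19 without hira-1(-) L4 replicate 1 and 2) and the cytochrome P450 gene cyp-14A2 (-4.47). K06H6.2 (-6.86) and F45D11.1 (-4.76) were the largest falls among genes with a sequence name only. In the other direction, msd-1, spp-9, oac-11 and C17A2.7 had no count in either N2 L4 library. Against a floor of 3 counts per library they were at least 177-fold, 48.9-fold, 47.7-fold and 50.7-fold higher in hira-1(-). The msd-1 call was lost with the replicate block (adjusted p = 0.208) and without hira-1(-) L4 replicate 1 or 2 (adjusted p = 0.0805 and 0.085), and this gene shares reads with copies. With 1 count over both N2 libraries, the ratio of hira-1(-) to N2 was 306 (95% interval 54.5 to 12120.2) for gtnt-9 and 675 (95% interval 121 to 26708) for ZK218.7, where intervals and floors cover counting error only. The F-box gene fbxa-158 (5.78, and 6.37 without N2 L4 replicate 1), gtnt-13 (5.46), numr-1 (4.55) and pals-14 (4.50) completed the 8 largest rises.

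In all, 9733 of 16770 genes differed at L4 by edgeR's quasi-likelihood test, 5951 higher and 3782 lower, of which 1852 and 973 changed at least 2-fold. Against a 1.5-fold minimum, 3170 genes passed. The genotypes' libraries did not overlap for 78.9% of genes, where chance gives 33.3%. The split of the calls moved with the scaling, the filter and the libraries in the fit. With TMM 61.1% were higher, with library totals 72.3% and on deposited log2 FPKM 72.5%. A minimum of 1 CPM in 3 libraries gave 50.9%, and a fit of the 4 L4 libraries 50.5%. Without N2 L4 replicate 1 and 2 the median log2 fold change of all genes was 0.0052 and 0.0057. Fits of fewer libraries also tested other genes, so what moved their values was not separated. The median log2 fold change of all genes was 0.10 with TMM and 0.24 with library totals, so changes are relative to that centre. Ribosomal RNA took 3.02% and 2.09% of the counts in N2 L4 and 2.91% and 2.26% in hira-1(-) L4.

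In adults, the question was again which genes differ between the genotypes. Sperm genes were lower in hira-1(-). Of 32 major sperm protein genes, 30 were lower and none was higher (median -1.81, interquartile range -1.99 to -1.57; adjusted p = 2.6e-45, and adjusted p = 0.142 with an estimated correlation). The gene msp-19 went from 120.2 ± 4.7 to 31.8 ± 0.0099 CPM (log2 fold change -1.92, SE 0.06, adjusted p = 9.6e-11) and msp-76 from 81.8 ± 1.2 to 19.7 ± 0.66 CPM (log2 fold change -2.05). Of 67 other sperm genes, 42 were lower and 1 higher (median -0.79; adjusted p = 1.8e-12, and adjusted p = 0.397 with an estimated correlation). Of these lists 31 and 43 members were lower adjusted over the list alone. Oocyte and eggshell genes did not pass as a list, with 7 higher and 7 lower of 27 (median 0.02, and -0.04 with RLE scaling; adjusted p = 0.831). Other germ line genes did not pass either, with 11 higher and 10 lower of 46 (median 0.06, and -0.01 with RLE scaling; adjusted p = 0.9). For cell cycle and replication genes the median was -0.10, and 0.11 with library totals (adjusted p = 0.256).

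Cuticle, hedgehog-related and molting genes were higher in hira-1(-) adults. Of 160 cuticle collagen genes, 103 were higher and 33 lower (median 2.02, and 1.86 with the 3 members that had a group at 0 set at their bound; adjusted p = 6.7e-31). The gene col-104 went from 6.71 ± 0.16 to 84.1 ± 1.7 CPM (log2 fold change 3.65, SE 0.08, adjusted p = 2.2e-12), against 1361 ± 86 CPM in N2 L4. The gene col-14 went from 9.33 ± 0.39 to 96.3 ± 3.8 CPM (log2 fold change 3.36), against 1480.4 ± 65 CPM in N2 L4. Of 43 hedgehog-related genes, 27 were higher and 6 lower (median 1.78; adjusted p = 1.1e-07), with grl-5 at 0.890 ± 0.041 to 10.2 ± 1.6 CPM and wrt-8 at 0.0776 ± 0.0083 to 4.95 ± 0.23 CPM. Of 47 molting genes, 30 were higher and 3 lower (median 0.49; adjusted p = 1.8e-07), with the patched-related genes ptr-4 at 1.33 ± 0.35 to 10.95 ± 0.034 CPM and ptr-18 at 2.42 ± 0.078 to 10.9 ± 0.84 CPM. None of these 3 lists passed with an estimated correlation (adjusted p = 0.142 with an estimated correlation for each). Adjusted over the list alone, 103, 28 and 30 members were higher. Of 12 heterochronic genes, which time larval development, 9 were higher and none was lower (median 0.45; adjusted p = 0.0493, and adjusted p = 0.451 with an estimated correlation; 9 higher adjusted over the list alone). The heterochronic call was lost with RLE scaling (adjusted p = 0.0558) and without N2 adult replicate 1 or 2 (adjusted p = 0.0684 and 0.0579).

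Yolk, ribosome and respiration genes were lower in hira-1(-) adults. Of 6 vitellogenin genes, 5 were lower (median -1.42; adjusted p = 0.0067, and adjusted p = 0.582 with an estimated correlation), with vit-1 at 4781 ± 514 to 1278 ± 201 CPM and vit-4 at 6612 ± 729.7 to 2589.8 ± 276 CPM. Of 75 ribosomal protein genes, 65 were lower by a small amount (median -0.32, and -0.12 with library totals; adjusted p = 2.4e-06, and adjusted p = 0.796 with an estimated correlation), among them rpl-35 (-0.49) and rpl-18A (-0.44). Of 40 respiration genes, 31 were lower (median -0.35, and -0.14 with library totals; adjusted p = 4.8e-06, and adjusted p = 0.463 with an estimated correlation). Adjusted over the list alone, 5, 67 and 31 members were lower. Body wall muscle genes did not pass as a list, with 14 lower and 6 higher (median -0.24, and -0.03 with library totals; adjusted p = 0.053).

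The H3.3 gene his-72 was higher in hira-1(-) adults, from 182 ± 4.5 to 379.9 ± 0.22 CPM (log2 fold change 1.06, SE 0.05, adjusted p = 6.0e-09), and so was his-71, from 20.6 ± 2.1 to 36.7 ± 1.3 CPM (log2 fold change 0.84). The log2 fold change of his-74 was -0.23 (adjusted p = 0.0018), and this call was lost with library totals (adjusted p = 0.736). For his-70 it was -0.32 (adjusted p = 0.156). Of the chaperone genes, hira-1, rba-1 (-0.14) and chaf-2 (-0.18) passed as lower. With library totals rba-1, chaf-2 and lin-53 were above 0 instead, and lin-53 (0.13, adjusted p = 0.0454), asfl-1 (adjusted p = 4.6e-04) and unc-85 (adjusted p = 0.0064) passed as higher. With RLE scaling lin-53 (-0.15, adjusted p = 0.0253), xnp-1 (adjusted p = 0.049) and chaf-1 (adjusted p = 0.0268) passed as lower, so the direction of lin-53 depends on the scaling. The rba-1 call was lost without N2 adult replicate 2 (adjusted p = 0.214) or hira-1(-) adult replicate 1 or 2 (adjusted p = 0.122 and 0.0926). The chaf-2 call was lost without N2 adult replicate 2 (adjusted p = 0.117) or hira-1(-) adult replicate 1 (adjusted p = 0.0787). For xnp-1 (-0.07), asfl-1 (0.10), unc-85 (0.01), lin-53 (-0.08) and chaf-1 (-0.09) the changes did not pass with TMM. The list did not pass (median -0.08, and 0.12 with library totals; adjusted p = 0.119). Of 58 core histone genes, 37 were higher and 5 lower (median 1.51; adjusted p = 9.4e-15, and adjusted p = 0.142 with an estimated correlation; 37 higher adjusted over the list alone). The gene his-11 went from 1.01 ± 0.18 to 32.2 ± 0.12 CPM and his-26 from 0.411 ± 0.13 to 16.1 ± 0.41 CPM. The genes his-52 and his-54 carried identical estimated counts, with 3.06 counts over both N2 adult libraries and a ratio of 152 (95% interval 51.7 to 740.1).

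The 8 largest falls in adults were led by the pud family. The gene pud-3 went from 919 ± 60.4 to 10.9 ± 1.3 CPM (log2 fold change -6.40, SE 0.10, adjusted p = 2.4e-13) and pud-4 from 202 ± 11 to 2.22 ± 0.58 CPM (log2 fold change -6.50). The genes pud-1.1 (-4.97), pud-1.2 (-4.75), pud-2.1 (-4.70) and pud-2.2 (-4.70) were lower as well, the last pair with identical estimated counts. The list went on with nspc-18 (-4.70) and the C-type lectin gene clec-197 (-4.03), and, with a sequence name only, C32H11.4 (-4.19) and T22B7.7 (-3.84). Among the rises, the non-coding RNA tts-1 went from 2.37 ± 1.1 to 178 ± 12 CPM (log2 fold change 6.26, SE 0.19, adjusted p = 1.5e-07). The flavin-containing monooxygenase gene fmo-2 went from 0.119 ± 0.067 to 7.07 ± 2.5 CPM (log2 fold change 5.88, and 6.49 without N2 adult replicate 1). The gene abu-1 had no count in N2 adult replicate 1 and 7.96 in replicate 2, against 292 and 272 in hira-1(-) adults. Its log2 fold change of 6.05 was 5.12 without N2 adult replicate 1, and without replicate 2 the N2 group is at 0, so the size rests on 1 library. With 1 to 3 counts over both N2 libraries, the ratio was 268 (95% interval 47.8 to 10636) for the saposin-like gene spp-21, 157 (95% interval 43.1 to 1301) for spp-9, 93.6 (95% interval 31.7 to 457) for idpp-12 and 1175 (95% interval 210.5 to 46449) for W07B8.4. W08E12.2 had no count in N2 adults and was at least 49.7-fold higher in hira-1(-).

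In all, 9235 of 16770 genes differed in adults, 4790 higher and 4445 lower, of which 2542 and 1053 changed at least 2-fold. Against a 1.5-fold minimum, 3443 genes passed. Of the calls, 51.9% were higher with TMM, 75.6% with library totals and 75.3% on deposited log2 FPKM. Most calls were lower instead with RLE scaling (44.8% higher), with DESeq2 (44.1%) and without N2 adult replicate 1 (46.1%). The median log2 fold change of all genes was 0.03 with TMM, -0.04 with RLE and 0.24 with library totals. Libraries of N2 adults had 12338 and 12256 genes at 1 CPM or more, and those of hira-1(-) adults 13401 and 13350. Ribosomal RNA took 1.82% and 0.602% of the counts in N2 adults and 0.702% and 0.392% in hira-1(-) adults.

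**Figure D1:**
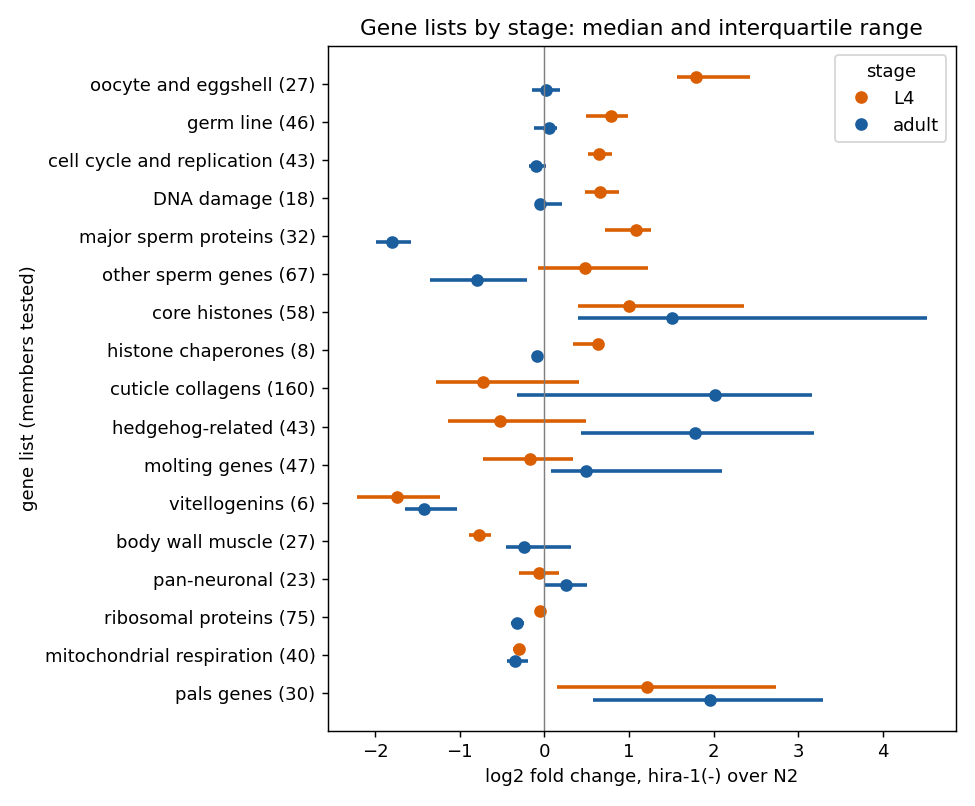
Median (point) and interquartile range (line) of the log2 fold change of hira-1(-) over N2 for the members of each gene list, at L4 (orange) and in adults (blue), on a linear axis. The cuticle collagens lie at a median of -0.73 at L4 and 2.02 in adults, and the major sperm proteins at 1.08 and -1.81. The adult medians of oocyte (0.02), germ line (0.06), histone chaperone (-0.08), DNA damage (-0.05) and cell cycle genes (-0.10) change sign with RLE scaling or library totals.

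The genotype differences of the 2 stages were compared by their interaction. Major sperm protein genes were relatively lower in adults (median difference in log2 fold change -2.91, 29 of 32 called), as were oocyte and eggshell genes (-1.83, 26 of 27), germ line genes (-0.67, 42 of 46) and cell cycle genes (-0.74, 39 of 43). Cuticle collagens were relatively higher in adults (1.85, 95 of 160), with hedgehog-related (2.06, 28 of 43), molting (1.15, 29 of 47) and body wall muscle genes (0.48, 18 of 27). The camera adjusted p lay between 4.2e-71 for the sperm and 5.2e-04 for the muscle list. With an estimated correlation none passed (adjusted p = 0.0886 with an estimated correlation for the major sperm protein, collagen, hedgehog-related and molting lists, adjusted p = 0.167 for oocyte, 0.245 for germ line, 0.145 for cell cycle and 0.597 for muscle genes). Adjusted over the list alone, 29, 26, 43 and 40 members were relatively lower and 97, 30, 30 and 18 relatively higher. The interaction passed for 8447 genes, 3467 relatively higher and 4980 relatively lower in adults (41.0% and, with a minimum of 1 CPM in 3 libraries, 49.9% higher), and for 3287 against a 1.5-fold minimum, of which 50.3% were relatively higher. Among the genes with the largest differences, the phosphatase gene cdc-25.3 was at 0.0368 ± 0.052 CPM, 2.73 ± 0.0040 CPM, 40.03 ± 1.4 CPM and 39.8 ± 3.1 CPM in N2 L4, hira-1(-) L4, N2 adults and hira-1(-) adults. Its difference of -6.07 was -5.06 and -9.25 without N2 L4 replicate 1 and 2, the last value set by the prior count as the N2 L4 group is then at 0. In the same order idpc-3 was at 26.4 ± 11 CPM, 13.5 ± 0.80 CPM, 0.194 ± 0.021 CPM and 8.24 ± 0.85 CPM. The genes sea-1, skr-7 and btb-6 had no count in N2 L4 and 0.384 ± 0.017 CPM, 0.366 ± 0.23 CPM and 0.801 ± 0.18 CPM in hira-1(-) L4. The genes gtnt-17 and grd-11 had no count in N2 adults and 0.0939 ± 0.080 CPM and 0.973 ± 0.12 CPM in hira-1(-) adults.

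**Figure D2:**
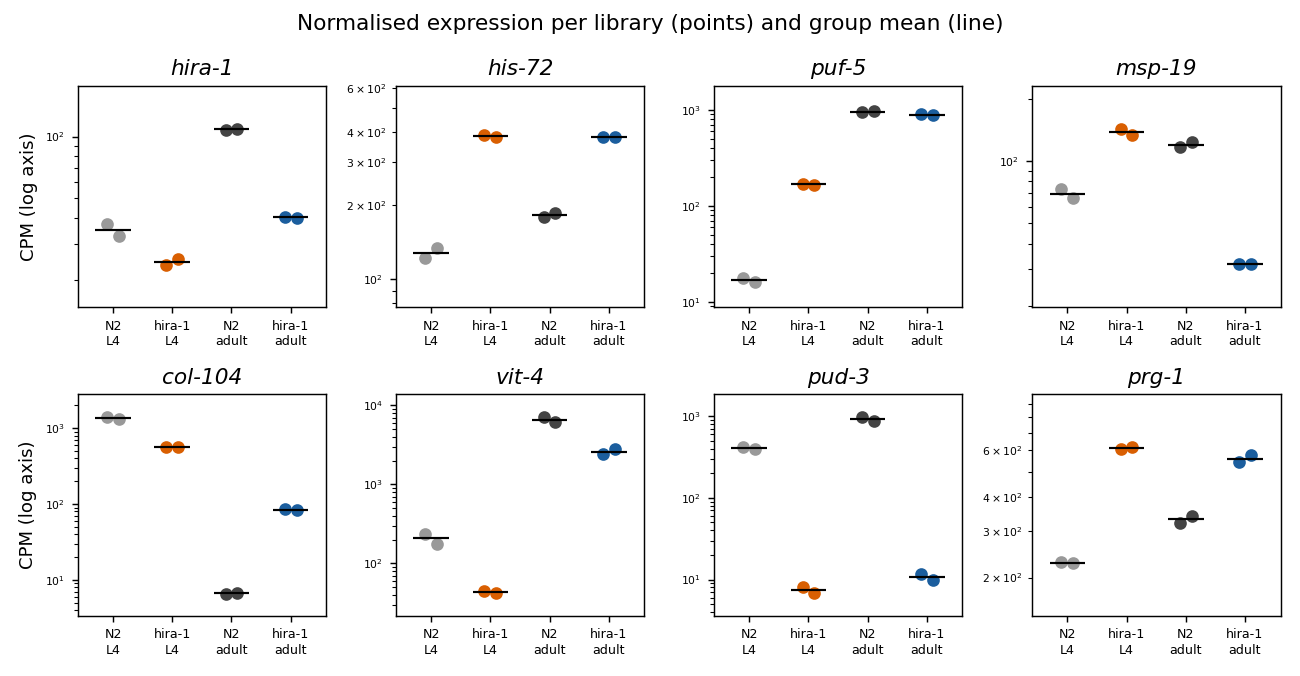
Normalised expression in CPM (log axis) of 8 genes in the 8 libraries (points) with the mean of each group (line, n = 2). The gene his-72 lies at a mean of 383 CPM in hira-1(-) L4 and 379.9 CPM in hira-1(-) adults, and pud-3 falls from 919 CPM in N2 adults to 10.9 CPM in hira-1(-) adults.

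Genes called at both stages were counted by direction. Of the 5951 genes higher at L4 and the 4790 higher in adults, 2136 were the same genes, where independent lists would share 1699.8 (odds ratio 1.72, 95% interval 1.61 to 1.85, Fisher's exact test, p = 8.6e-54). Of the 3782 and 4445 lower genes, 1591 were shared against 1002 by Fisher's exact test (odds ratio 2.58, 95% interval 2.39 to 2.79, p = 7.9e-126). Genes changed at least 2-fold the same way at both stages numbered 767 higher and 321 lower. Of the 1434 genes changed at least 2-fold at both stages, 8.58% were higher at L4 and lower in adults and 15.6% the reverse. Without a minimum fold the order of these was the opposite: 1362 genes were higher at L4 and lower in adults, where independent lists would share 1577, and 867 were lower at L4 and higher in adults, against 1080.2. With DESeq2 calls the last count did not differ from chance (634 against 644, Fisher's exact test, p = 0.624). Across genes, the log2 fold changes of the stages correlated at r = 0.352 (Spearman 0.206), and among the 10549 genes with a mean of at least 5 CPM at r = 0.165 (Spearman 0.145). Genes are not independent replicates, so these p-values describe the lists, and the stages share no library. The shared genes were ranked by the mean of their fitted changes, which the prior count sets where a group is at 0, so the rank favours genes without counts in N2. Of the first 10, pud-4 was lower and the others were higher, and pud-3, with log2 fold changes of -5.77 and -6.40, was not among them. The glutamine and asparagine-rich gene pqn-57 was at least 14.8-fold higher at L4 and at least 25.5-fold in adults, fbxa-164 at least 7.49-fold and at least 19.9-fold, and the homeobox gene ceh-84 at least 2.90-fold and at least 7.06-fold. In adults, oac-11, gtnt-9 and oac-4 were at least 3.37-fold, at least 4.82-fold and at least 2.09-fold higher, and cyp-33D3 at least 23.7-fold, with cyp-33D3 at a log2 fold change of 3.32 at L4. At L4, oac-4 was 171-fold (95% interval 30.3 to 6786) and spp-21 197-fold (95% interval 34.9 to 7802) higher, and spp-9 was among the 10 as well.

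The stages of N2 served as the background for these differences. From L4 to adults, all 27 oocyte and eggshell genes (median log2 fold change 4.32) and all 6 vitellogenin genes (5.04) were higher. Of the cuticle collagens, 103 of 160 were lower (median -3.79, and -3.64 with 2 members set at their bound), and of the hedgehog-related genes 35 of 43 (-4.89). The camera adjusted p was 4.1e-43, 0.0035, 6.0e-23 and 8.4e-14, against an adjusted p = 0.165, 0.624, 0.213 and 0.133 with an estimated correlation. The counts adjusted over the list alone were 27 and 6 higher and 103 and 35 lower. In all 13679 genes differed, 6408 higher and 7271 lower in adults (46.8% higher, and 50.7% with DESeq2). The median of all genes was -0.15 with TMM and -0.32 with library totals. With no count in N2 L4, sea-1, skr-7, btb-6 and ssp-37 were at least 156-fold, 120.1-fold, 109.8-fold and 87.3-fold higher in adults. With no count in N2 adults, gtnt-17, grd-11 and oac-42 were at least 261-fold, 61.3-fold and 43.5-fold lower. The cuticle collagen gene sqt-2 went from 901 ± 28 to 1.30 ± 0.42 CPM (log2 fold change -9.40).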

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

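Apart from the test of how evenly L4-stage genes appear in adults, the tests of explanations in this part were chosen after the results were seen. The difference between the genotype effects of the stages passed for 8447 genes, and each value below is the log2 fold change of hira-1(-) over N2 in adults minus that at L4, with an adjusted p under the threshold.

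Among histone genes the difference was his-71 (0.65), his-74 (-0.85), his-72 (-0.52), his-11 (2.31), his-26 (1.41), his-54 (4.79) and his-52 (4.79). Among chaperone genes it was xnp-1 (-0.42), asfl-1 (-0.90), unc-85 (-0.62), rba-1 (-0.81), lin-53 (-0.70), hira-1 (-0.91), chaf-1 (-0.75) and chaf-2 (-0.49). Among germ line genes it was msp-45 (-2.97), msp-38 (-3.21), puf-5 (-3.40), puf-3 (-2.31), prg-1 (-0.68), hrde-1 (-1.17), cyb-2.1 (-2.33), cyb-2.2 (-2.07), msp-19 (-2.91), msp-76 (-3.23) and cdc-25.3 (-6.07). Among cuticle, molting and hedgehog-related genes it was col-38 (4.59), col-175 (4.64), col-104 (4.92), col-14 (4.62), ptr-4 (3.23), ptr-18 (2.95), grl-5 (4.62) and wrt-8 (4.98). Among the other named genes it was numr-1 (-1.08), pud-3 (-0.63), gly-1 (3.99), gtnt-18 (4.36), cyp-14A2 (1.92), pud-1.1 (-0.76), pud-1.2 (-0.67), F45D11.1 (1.81), vit-3 (1.53), vit-4 (0.91), act-1 (0.69), dim-1 (0.48), idpp-12 (3.52), tts-1 (4.37), abu-1 (7.20), W07B8.4 (5.21), pud-2.1 (-0.78), pud-2.2 (-0.78), C32H11.4 (-1.85), T22B7.7 (-2.41), vit-1 (-0.98), pals-6 (1.497), rpl-35 (-0.39), rpl-18A (-0.32) and idpc-3 (6.35). For gtnt-17 (9.15), grd-11 (7.63), btb-6 (-7.75), sea-1 (-6.43), skr-7 (-5.76) and W08E12.2 (5.42) the fitted value depends on the prior count, since a group of each was at 0. The value of abu-1 was 6.38 without N2 adult replicate 1 and 12.33 without replicate 2, and that of cdc-25.3 was -5.06 without N2 L4 replicate 1 and -9.25 without replicate 2. The second value of each depends on the prior count, as only the library left out had counts in that group. Without hira-1(-) adult replicate 1 and 2 gtnt-17 was at 9.82 and 7.92, and without hira-1(-) L4 replicate 2 skr-7 was at -4.90. Through the adult or L4 log2 fold change that enters them, the values of his-54, his-52, W07B8.4 and gly-1 also rest on few counts. Without N2 adult replicate 1 and 2 the adult fold change was 10.91 and 6.08 for his-54 and his-52, in place of 7.14, and 12.27 and 8.93 for W07B8.4, in place of 9.89, the first of each set by the prior count. Without hira-1(-) L4 replicate 1 and 2 that of gly-1 at L4 was -3.98 and -6.19, in place of -4.69. Median differences of lists were -2.91 for major sperm proteins, -1.83 for oocyte and eggshell genes, -1.49 for other sperm genes, -0.74 for cell cycle genes, -0.73 for histone chaperones, -0.71 for DNA damage genes, -0.67 for germ line genes, -0.43 for small RNA pathway genes and -0.28 for ribosomal proteins. They were 2.06 for hedgehog-related genes, 1.85 for cuticle collagens, 1.15 for molting genes, 0.72 for pharynx genes, 0.64 for core histones, 0.48 for body wall muscle, 0.47 for neuropeptides, 0.42 for intestine genes and 0.19 for antimicrobial and defence genes. All these list calls were lost with an estimated correlation (adjusted p between 0.0886 and, for the ribosomal proteins, 0.86). The call of the antimicrobial and defence list was also lost with fry (adjusted p = 0.0615), with library totals (0.0688) and without N2 L4 replicate 2 (0.227), hira-1(-) L4 replicate 2 (0.0517), N2 adult replicate 2 (0.0866) or hira-1(-) adult replicate 1 (0.0774). That of the neuropeptides was lost with fry (adjusted p = 0.0838) and without N2 L4 replicate 1 or 2 (0.115 and 0.0628), N2 adult replicate 2 (0.059) or hira-1(-) adult replicate 1 (0.0972). That of the ribosomal proteins was lost with library totals (adjusted p = 0.0692) and without N2 L4 replicate 1 (0.314), N2 adult replicate 2 (0.086) or hira-1(-) adult replicate 1 (0.0619).

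Genes of the L4 stage were higher in hira-1(-) adults than in N2 adults. Of 246 genes at least 5 log2 units lower in N2 adults than in N2 L4 and at 20 CPM or more in L4 of both genotypes, 98.4% were higher. They lay at a median of 7.45% of their hira-1(-) L4 level (4.49% of their N2 L4 level). Choosing genes low in N2 adults favours this direction. Of 246 and 244 genes chosen with 1 N2 adult library, 98.8% and 100% were above the other in both hira-1(-) libraries. This split removes only the noise of single libraries. Genes chosen as low in 1 N2 adult library are low in its replicate too, so the choice still favours a rise. Animals like those sampled at L4 among the adults would bring these genes in at one share, but the 75th percentile of the share was 2.67 times the 25th (95% bootstrap interval 2.14 to 3.06 over genes; 2.70 and 2.63 with genes chosen on 1 library), above the bound of 2 set in advance. Such animals would also change the vitellogenins in adults by -0.11 on the log2 scale, and the measured median lay -1.31 beyond that. This bears only on the vitellogenins, which were also lower at L4 (median -1.74), and not on the source of the L4-stage genes. By list, the quartiles of the share of the hira-1(-) L4 level were 4.72 and 6.64% for 13 hedgehog-related genes and 4.76 and 6.66% for 11 molting genes. They were 6.39 and 17.5% for 55 collagens, 8.67 and 26.1% for 5 pharynx genes and 4.76 and 11.3% for 160 genes in no list. The spread thus argues against animals like those sampled at L4 as the only source. A smaller share of them beside changes in some genes stays open. Scaling moved the collagen median to 1.95 at the lowest. Larvae of another age, slower development of some animals and an effect of the genotype on these genes stay open, since no library of another age was analysed. Nearly all L4-stage genes moved the way that a mixture of ages would move them, a direction that their choice favours.

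Oocyte genes were higher in hira-1(-) L4. Suppose that adults like those sampled were among the L4 animals and gave all of their vitellogenin. Their share of the RNA would then be 2.32% by the median of the 6 vitellogenins (from 0.728 to 5.73%). The oocyte genes need a median of 14.6% (interquartile range 12.2 to 16.5%, lowest 3.23%), so such adults do not account for the list as a whole. The lowest need lay above the lowest and the median share allowed, and below the highest. If such adults held all 6 vitellogenins in the sampled proportions, the lowest share, 0.728%, would be the limit. The median of the oocyte list stayed at 1.78 or above with RLE scaling and library totals, so scaling does not account for it. A lower share of somatic RNA as a whole would by itself lower all somatic markers alike. The medians of the muscle, pan-neuronal, pharynx and intestine lists spread over 0.71 log2 units. They ran from -0.77 for muscle to -0.06 for pan-neuronal genes, with separate interquartile ranges. A uniform fall alone thus does not give these values, but a lower somatic share beside changes in single tissues stays open. A larger germ line would give such a share. Larvae slightly older than those of N2, a larger germ line and an effect of the genotype on oocyte genes stay open and were not tested.

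Core histone genes were higher in hira-1(-) at both stages. Reads shared between copies would leave their sum as it was, but the sum over 65 genes went from 341 ± 19 to 515 ± 7.1 CPM at L4, 1.51 times and so above the bound of 1.5 by less than its spread, and from 219 ± 4.2 to 447 ± 4.9 CPM in adults, 2.05 times (SD, n = 2). Against more carry-over of RNA without a poly(A) tail, the ribosomal RNA share of hira-1(-) was 1.01 times that of N2 at L4 and 0.452 times in adults, and at most 1.39 and 1.17 times between any 2 libraries, under the histone ratios, but this stays open, as 1 hira-1(-) adult library lay above 1 of N2 and histone RNA need not be carried over like ribosomal RNA. More dividing cells may be part of it at L4, where the cell cycle list had a median of 0.65 beside 1.00 for the histones, while in adults its median was -0.10 and its level in N2 adults is high enough to hide a small share of such cells. An effect of the hira-1 allele on histone genes was not tested.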

How the results depend on the processing

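Library totals, fits without ribosomal RNA genes, the split-control comparison of stages and the choice of L4-stage genes on 1 library were added after seeing the data. Against a 1.5-fold minimum the counts of genes fell to 3170 at L4, 3443 in adults and 3287 for the interaction, since this test asks for more than any change. For the N2 stages it gave 10169. With an estimated correlation 0 lists passed in any comparison, where the preset one gave 21 at L4, 16 in adults, 18 for the interaction and 16 for the N2 stages, and fry gave 26, 27, 24 and 32. At an unadjusted p under 0.05 the estimated correlation gave 7, 6, 7 and 8 lists. At L4 the estimated correlation was 0.667 for the oocyte list and 0.475 for the major sperm proteins, against the preset 0.01. For the pals genes it was -0.0186, and their unadjusted camera p still rose from 0.0038 to 0.0303. For the hedgehog-related genes at L4 it was -0.0017, and their unadjusted p rose from 7.5e-04 to 0.0159. A higher correlation is thus not the whole cause. With an estimated correlation camera is also limited to the 4 residual degrees of freedom of the fit, which the preset correlation is not. The parts of these 2 were not separated, so a lost list call does not by itself show correlated genes. The shared higher genes numbered 1280 among genes with a mean of at least 5 CPM, where independent lists would share 1173 (odds ratio 1.24, against 1.72 over all genes), and 1351 with DESeq2, whose lists are shorter, against 987 (odds ratio 1.84). All other alternatives left the total counts within 1.5 times. By direction, library totals gave 7198 higher and 2320 lower genes in adults and limma on FPKM 2265 lower, against 4790 and 4445.

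Leaving out 1 library gave 7906 to 8818 genes at L4, 7424 to 8397 in adults, 7149 to 8092 for the interaction and 12884 to 13400 for the N2 stages, with the lone library assumed to vary like the other groups. The hira-1 log2 fold change lay between -0.71 and -0.47 at L4 and between -1.49 and -1.42 in adults, past the threshold each time. The labels do not say that libraries with the same replicate number share a day or culture. Deviations of same-numbered libraries correlated between -0.0029 and 0.0661. Replicate 1 had the higher ribosomal RNA share in each group, however, so something shared by the number is not excluded. With the replicate block 9694, 9134, 8349 and 13680 genes passed at L4, in adults, for the interaction and for the N2 stages. Of the named genes, only the msd-1 call was lost with the block.

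Over 912 values of named genes under alternatives, 889 kept direction and side of the threshold, 15 lost the call, 5 gained one and 3 reversed. The reversed ones were adult values with library totals: rba-1 (0.0645), lin-53 (0.13) and chaf-2 (0.0254), as that scaling moves the centre of all genes. Of 55 list calls at L4, in adults and for the interaction, 10 were lost in some alternative other than the estimated correlation. The settings written for L1 and for the stage axis were not run, as no L1 column matched a label. In simulated data with 200 changed genes, 84% of 2-fold changes were recovered at L4, 84% in adults and 56% for the interaction. Fewer of the smaller changes were recovered, so a gene without a call is not shown to be unchanged.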

Other observations

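Genes of the pals family, some of which are induced by intracellular infection in wild-type animals, were higher in hira-1(-) at both stages. At L4 18 of 30 were higher and none lower (median 1.22; adjusted p = 0.0085, and adjusted p = 0.216 with an estimated correlation). In adults 22 were higher and 1 lower (median 1.95; adjusted p = 4.4e-05, and adjusted p = 0.142 with an estimated correlation). The gene pals-6 went from 0.152 ± 0.038 to 7.24 ± 0.31 CPM and pals-14 from 0.218 ± 0.11 to 6.56 ± 0.47 CPM in adults. Of 376 F-box and MATH/BTB genes, 151 were higher and 24 lower at L4 (median 0.58, and 0.38 with 62 members set at their bound; adjusted p = 0.0412, and adjusted p = 0.24 with an estimated correlation). In adults 156 were higher and 23 lower (median 0.57; adjusted p = 0.0046, and adjusted p = 0.32 with an estimated correlation). The F-box list's call was lost with library totals at L4 (adjusted p = 0.261) and in adults (adjusted p = 0.103), and at L4 without hira-1(-) L4 replicate 1 or 2 (adjusted p = 0.0509 and 0.0623). Of 53 small RNA pathway genes, 42 were higher and 7 lower at L4 (median 0.39; adjusted p = 7.1e-06, and adjusted p = 0.24 with an estimated correlation). Adjusted over the list alone, 18 and 23 pals genes, 142 and 153 F-box and MATH/BTB genes at L4 and in adults, and 42 small RNA genes at L4 were higher. Antimicrobial and defence genes did not pass at L4 (34 higher, 28 lower; adjusted p = 0.385) or in adults (51 higher, 29 lower; adjusted p = 0.0591).

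Other lists passed at 1 or both stages. Of 31 chromatin regulator genes, 26 were higher and 1 lower at L4 (median 0.55; adjusted p = 1.1e-06, and adjusted p = 0.24 with an estimated correlation). In adults 13 were higher and 1 lower (median 0.10, 0.31 with library totals and 0.03 with RLE scaling; adjusted p = 0.0028, and adjusted p = 0.467 with an estimated correlation). Of 82 pharynx genes, 45 were higher and 9 lower in adults (median 0.76, and 0.65 with members that had a group at 0 set at their bound; adjusted p = 7.1e-04, and adjusted p = 0.745 with an estimated correlation). Of 87 fatty acid metabolism genes, 47 were lower and 18 higher in adults (median -0.26, and -0.05 with library totals; adjusted p = 1.6e-04, and adjusted p = 0.397 with an estimated correlation). Of 18 ER stress genes, 11 were lower and 1 higher at L4 (median -0.18; adjusted p = 0.0146, and adjusted p = 0.24 with an estimated correlation), a call lost with library totals (adjusted p = 0.0739). Of 34 intestine genes, 19 were lower and 8 higher at L4 (median -0.22; adjusted p = 0.0255, and adjusted p = 0.739 with an estimated correlation). In adults 15 were higher and 10 lower (median 0.13; adjusted p = 0.0434, and adjusted p = 0.861 with an estimated correlation). The intestine call at L4 was lost with fry (adjusted p = 0.0771), library totals (adjusted p = 0.0739) and without N2 L4 replicate 2 (adjusted p = 0.199) or hira-1(-) L4 replicate 1 (adjusted p = 0.0511), and that in adults without N2 adult replicate 1 or 2 (adjusted p = 0.08 and 0.116). Members called when adjusted over the list alone were 27 and 13 chromatin regulators higher at L4 and in adults, 46 pharynx genes higher and 49 fatty acid genes lower in adults, 11 ER stress genes lower at L4, and 19 intestine genes lower at L4 and 15 higher in adults.

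Genes changed at least 4-fold at both stages lay next to each other more often than shuffled labels gave, a count chosen after the names of the largest changes were seen. Of 16458 tested genes put in the order of the WBcel235 annotation, 336 were higher at both stages, and 75 pairs of them were neighbours, against a mean of 6.85 and a highest value of 16 over the shuffles (one-sided permutation p = 0.0001, the smallest they can give). Without pairs that share a name stem, such as members of one gene family, the number was 53 against 6.48 (permutation p = 0.0001). Of 111 genes lower at both stages, 24 pairs were neighbours against 0.743, and 6 against 0.694 without shared name stems (permutation p = 0.0001 each). Neighbouring genes are not independent, and relatives that carry a sequence name only were not removed.

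The genotype differences were also set beside the N2 difference of adults minus L4, a comparison chosen after seeing the data, in which 1 N2 library of the stage entered the genotype difference and the other the stage difference. Across 16770 genes the adult genotype difference correlated with it at r = -0.363 and -0.357 for the 2 ways of splitting the libraries (Spearman -0.256 and -0.278). The L4 genotype difference correlated with it at r = 0.385 and 0.382 (Spearman 0.437 and 0.400). Both differences hold the N2 group of the stage. A deviation common to its 2 libraries would give a negative correlation in adults and a positive one at L4, the signs found. The split of libraries does not remove this, so the values do not show that the genotype difference lies along the stages. Genes are not independent replicates, and no p-value is given.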
